A study of Mus musculus with 6 samples.

How the data were processed

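Gene expression in whole mouse liver was measured by RNA sequencing in 6 samples. According to the labels, 3 came from mice in which loxP-flanked Dicer alleles were deleted by a Cre recombinase driven by the albumin promoter, which is active in hepatocytes (Dicer LKO), and 3 from controls, all about 1 month old and of the C57BL/6 strain. Total RNA was extracted with Trizol from frozen liver, per the labels' protocols, and the libraries followed Illumina's usual procedure; the kit, the read length and the strand setting are not given in the sources used here. The groups and the replicate numbers were taken from the sample titles. Nothing beyond these labels shows that the samples came from separate animals, so all p-values measure the spread between these samples, which may be partly technical.

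The authors deposited 1 table per sample with an expected count (the estimated number of reads per gene, not normalized) and a TPM value (transcript abundance corrected for effective gene length and scaled to the same total in each sample, by the authors) for 50600 genes, plus 1 table of the whole series. Every value of the series table equalled the deposited expected count of the same gene and sample (100% of values), and no further sample columns were present. Per the submitters' processing notes, CASAVA and Bowtie were used, without versions, and the genome build was hg19, which is human, although the gene identifiers in the deposited tables are mouse. The program that assigned reads to genes, the mouse build and the annotation are not given in the sources used here; per the file headers, the columns are those written by RSEM. Of the gene identifiers, 50376 (99.56%) matched GENCODE release M21 (mouse build GRCm38), from which all coordinates, gene types and 3′ untranslated regions were taken. An expected count shares ambiguous reads among similar genes by a model, so values of near-identical genes (the haemoglobin, Mup, Serpina1, Cyp2, Cyp3a and Cyp4a families and the 7SL genes Rn7s1 and Rn7s2) are uncertain. Because the strand setting is unknown, the same holds for overlapping and antisense genes.

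The deposited expected counts were rounded to whole numbers; about 96.0% to 96.5% of them were whole already. The totals per sample were 22257541, 23436696 and 25049749 in Dicer LKO replicates 1, 2 and 3, and 22152506, 20539847 and 14141973 in control replicates 1, 2 and 3. Floors for a count of 0 are set at 3 counts per library and cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of libraries held identical values, and the chi-square per gene between libraries was 26.1 or more, so each sample was counted as 1 replicate.

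The choices in this paragraph and the next were made before the data were examined. Genes were filtered with filterByExpr, scaled with TMM factors and tested with edgeR's quasi-likelihood test (glmQLFit with the robust setting, and glmQLFTest; edgeR 4.0.16, R 4.3.3) with genotype as the only term; a gene was called at a Benjamini-Hochberg adjusted p under 0.05. All adjusted p-values in the text come from this fit unless another tool is named. Values per library are CPM (counts scaled by library size and TMM factor) computed from the rounded counts. For single values, an exact two-sided permutation test was used, which cannot give less than 0.1 for 3 against 3. The named genes were Dicer1, then the 10 higher and 10 lower called genes with the largest log2 fold changes among those with an average log2 CPM of at least 1, no overlap between the groups' libraries and a symbol other than a predicted-gene or clone name, then up to 4 called members of each fixed list, or up to 2 members with the highest expression where fewer than 2 were called.

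A set of 38 gene lists (pathways, liver functions, sex-biased genes, reported miRNA targets and markers of other cell types) was written from general knowledge. Lists with at least 5 tested members were tested with fry and with camera (limma 3.58.1). Camera was run with a preset correlation of 0.01 between genes and with an estimated correlation. Its p-values were adjusted over the lists by Benjamini-Hochberg. With an estimated correlation, camera also uses the residual degrees of freedom of the fit (4 with all libraries), which makes it stricter apart from any correlation. A call lost in that setting therefore cannot be put down to correlation between genes alone. Genes with a site for each of 29 miRNA seed families in the longest annotated 3′ untranslated region (a 7mer-m8 match, that is, positions 2 to 8 of the miRNA) were tested in the same way against other genes with a 3′ untranslated region. The median log2 fold change of each family was set beside 10000 random lists matched on untranslated region length and expression.

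The pipeline was tested on simulated data: in 5 simulations with the means and depths of these samples and 14314 genes, 200 of them changed, the test called 81.9% and 89.2% of genes changed by −2 and 2 on the log2 scale, and 29.6% and 35.2% of those changed by −1 and 1. Of the calls, 8.76% were unchanged genes, above the 5% aimed at. A simulated list moved by 1 was called with an adjusted p of 1.07e-67 by camera, with 0 of 35 other lists called. Genes were simulated independently of each other, whereas estimated correlations in the real lists reached 0.776. The simulation therefore cannot show how often correlated lists are called in error.

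The alternatives fixed in advance were RLE size factors, library totals, no filter on low counts, a CPM of at least 1 in 3 libraries, DESeq2 1.42.0, limma on log2(TPM + 1) for genes with a mean TPM of at least 1, the series table, the replicate number as a block, each sample left out in turn, an absolute log2 fold change of at least 1, an estimated correlation and 8mer sites. Added after the data were seen were limma's voom with sample quality weights and a term for libraries with and without transcripts of heart muscle. Small RNAs themselves were not analysed here, and a few genes that the rule or the lists name are not reported here.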

Results

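RNA from whole liver of mice about 1 month old was sequenced in 3 samples with Dicer deleted in hepatocytes (Dicer LKO, n = 3) and 3 control samples (n = 3). Dicer cuts miRNA precursors into mature miRNAs, and the comparison asks how the liver's messenger RNAs differ when hepatocytes lack it. The tables held 22257541, 23436696 and 25049749 counts for Dicer LKO replicates 1, 2 and 3, and 22152506, 20539847 and 14141973 for control replicates 1, 2 and 3, so control replicate 3 was the shallowest. Mitochondrial genes took 10.2% of its counts, against 4.62% to 6.46% in the other libraries. Correlations of log2 CPM across genes, which are not independent replicates, were 0.957 to 0.984 within groups and 0.917 to 0.962 between them.

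Dicer1 itself (ENSMUSG00000041415.9, chromosome 12, 104687742 to 104751952, minus strand, GRCm38) was measured at 28.9, 31.2 and 24.4 CPM in the Dicer LKO libraries and at 42.5, 69.2 and 56.1 CPM in the controls. The means were 28.2 ± 3.46 CPM (SD, n = 3) and 56.0 ± 13.4 CPM (SD, n = 3), so that the Dicer LKO mean was 50.3% of the control mean. All 3 Dicer LKO libraries lay below all 3 controls, in the direction of the labels. The exact two-sided permutation p was 0.1, the smallest that 3 against 3 allows. The log2 fold change was −0.99 (SE 0.20) with an adjusted p of 0.0622 by edgeR's quasi-likelihood test, which missed the threshold. Without control replicate 1 the same test gave −1.15 with an adjusted p of 0.0327. Here and below, the SE is the absolute log2 fold change divided by the square root of the test's F statistic. The counts cover the whole gene and every liver cell type, so the deleted part was not measured separately.

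The livers with deleted Dicer held more transcript of Sult1e1, an oestrogen sulfotransferase (37.9 ± 28.0 against 0.111 ± 0.155 CPM, mean ± SD, n = 3 each), of the matrix protease Mmp7 (5.25 ± 2.02 against 0.0320 ± 0.0555 CPM) and of the fatty acid hydroxylase Cyp4a14 (144 ± 81.5 against 3.52 ± 2.07 CPM). Apoa4, a lipoprotein component, rose from 70.9 ± 17.3 to 1024 ± 881 CPM, and the guanylate cyclase receptor Gucy2c from 1.1 ± 0.45 to 12.3 ± 0.637 CPM. Among the genes that fell, Pclo, which encodes a scaffold protein of presynaptic terminals, went from 4.33 ± 2.39 to 0.120 ± 0.0351 CPM. Dpy19l3, a mannosyltransferase, fell from 30.1 ± 4.73 to 2.85 ± 0.995 CPM and the major urinary protein gene Mup21 from 108 ± 38.7 to 15.9 ± 4.65 CPM. By the list test with a preset correlation, markers of red blood cells, macrophages, bile duct cells and matrix-producing cells were higher as groups, female-biased liver genes were higher and male-biased ones lower. With an estimated correlation, only the sex-biased lists passed camera (adjusted p = 0.0491 for each). That setting is stricter in more than correlation. Stellate cell and fibroblast markers, with an estimated correlation of −0.028, went from a camera adjusted p of 3.21e-07 to 0.054. The marker lists had adjusted p-values of 0.054 to 0.332 there. Fry was not adjusted over the lists. It gave values under 0.05 for the sex-biased, erythroid, macrophage, ductular, stellate, matrix, endothelial, fetal liver and small RNA pathway lists. It missed 0.05 for the other lists called by camera, among them acute phase, neutrophil, cell cycle and both lipid synthesis lists. Imprinted genes, reported miR-122 targets and hepatocyte transcription factors passed fry without a camera call.

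Of 14314 genes tested, 185 changed, 79 of them lower and the other 57.3% higher in Dicer LKO (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05). Protein-coding genes made up 156 of them (84.3%), and 163 changed by at least 1 on the log2 scale (101 higher, 62 lower). At an unadjusted p under 0.05 there were 3002 genes, where 716 are expected by chance. The groups' libraries did not overlap for 4014 genes (28.0%), against 10% by chance. Both chance values are averages. Because genes vary together, a given split can lie far from them without an effect of genotype. The number called depended on single libraries: it was 39, 92 and 31 without Dicer LKO replicates 1, 2 and 3, and 389, 61 and 23 without control replicates 1, 2 and 3. The balance of directions turned in some settings. Higher genes made up 19.5% of calls without control replicate 1 and 65.2% to 82.1% without each other library, 48.5% with library totals, 49.1% without a filter, 44.3% with DESeq2 and 30% with voom sample weights. Every one of the 185 genes kept its sign in each of these fits. The fits reuse the libraries from which the 185 genes were picked, so this was largely fixed in advance.

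Log2 fold changes of the 10 higher genes named for the largest changes ran from 8.25 for Sult1e1 (SE 1.18, adjusted p = 0.0470, edgeR quasi-likelihood) to 3.05 for Hbb-bt. Among those between them were Mmp7 (7.04, from 365 counts against 2, a ratio of 158 with an exact 95% interval of 43.4 to 1310 for counting error only), Cyp4a14 (5.35), Cyp3a44 (4.4), the erythrocyte anion exchanger Slc4a1 (3.90), Apoa4 (3.85), Gucy2c (3.45) and the neurotrophin receptor Ntrk2 (3.22). Among the 10 lower genes that the fixed rule took from the called genes, the largest falls were those of Pclo (−5.11, SE 0.57), Dpy19l3 (−3.40), the atypical MAP kinase Mapk15 (−3.34), Cabyr (−3.01) and the zinc finger gene Zfp982 (−2.87). Mup21 (−2.76), Col25a1 (−2.71), the cytochrome P450 gene Cyp2u1 (−2.24), the acetyltransferase gene Nat8 (−2.22) and the elastase gene Cela1 (−1.98) completed the 10 named lower genes. Col25a1 overlaps the transcript Gm43210 on the same strand, and Cyp3a44 and Mup21 have close paralogs, so their values are uncertain. Of 40 called genes named by the fixed rule, Mmp7, Gucy2c and Lum kept their call in every setting. Without Dicer LKO replicates 1, 2 and 3, 21, 11 and 27 named calls were lost, and without control replicates 1, 2 and 3, 8, 22 and 29. Other genes named in the text, outside the fixed rule, were chosen after their values were seen.

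**Figure D1:**
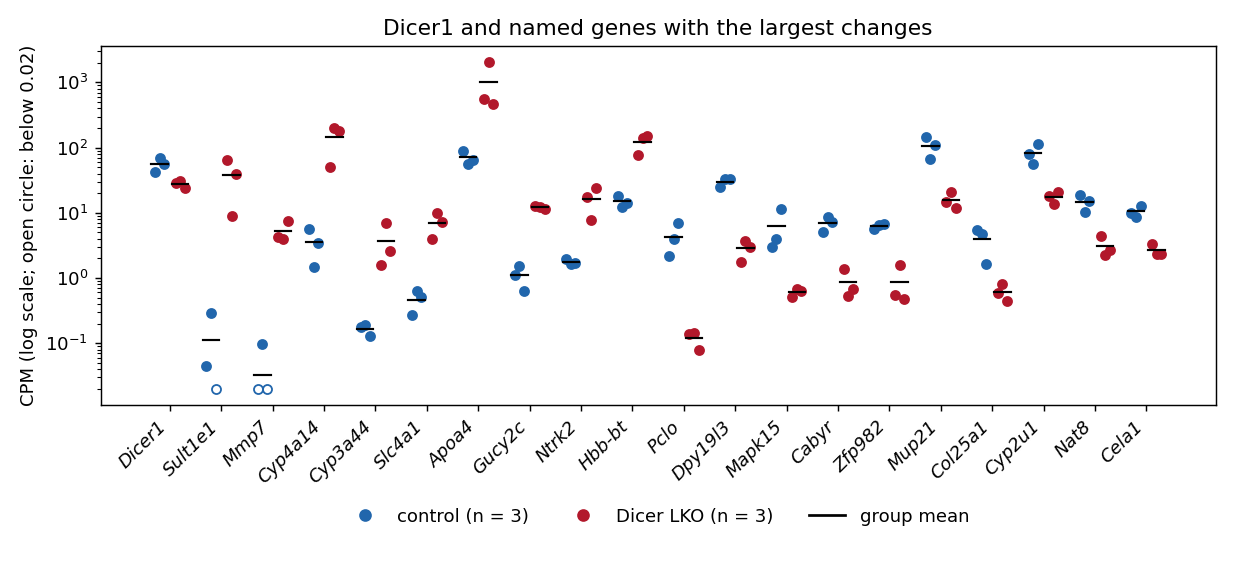
CPM of Dicer1 and 19 of the named genes with the largest changes in each library (log scale; points are libraries, n = 3 per group, bars are group means, and open circles stand for values below the axis). Gucy2c was at 11.6 to 12.8 CPM in the Dicer LKO libraries and 0.638 to 1.54 CPM in the controls.

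Sex-biased liver genes moved in opposite directions. The male-biased list had 18 tested members, with a median log2 fold change of −2.14, and 17 of them had a negative value. That of 1 of these, Serpina1e (−8.18, not called), came from control replicate 2 alone. Mup21 fell over all genes, and 13 members were lower adjusted over the list alone. Mup7 was at 619 ± 606 against 2728 ± 684 CPM (adjusted p = 0.168, edgeR) and Mup20 at 1342 ± 677 against 2794 ± 349 CPM (adjusted p = 0.183). Of 18 female-biased genes, 10 passed the filter on low counts, and 8 of these had positive values. Among the 10 tested, 3 rose and 6 were higher adjusted over the list alone, with a median of 2.46. A gene near 0 in the controls, such as Cyp3a44 (4, 4 and 2 counts), passes the filter only if it is high in Dicer LKO. The filter thus favours rises in this list, and other lists that lost members to it are open to the same kind of bias. The risers were Cyp3a44, the transcription factor gene Cux2 (2.75) and the oxysterol hydroxylase Cyp39a1 (1.82, from 11.8 ± 3.0 to 41.6 ± 5.23 CPM). Cyp3a41a had 0 counts in every control and 6.76 ± 6.04 CPM in Dicer LKO, at least 43.1-fold higher against a floor of 3 counts per library (adjusted p = 0.0822, edgeR), and the list's median was 2.46 with this gene at its floor. Both lists were called by camera (adjusted p = 9.23e-14 and 1.83e-10), and they were the only 2 of the 19 called lists that also passed with an estimated correlation (adjusted p = 0.0491 with an estimated correlation for each). Without each library in turn, the medians were −2.36 to −1.80 for the male-biased and 1.79 to 3.14 for the female-biased list. The estimated-correlation call was nevertheless lost without any 1 of the 6 libraries (adjusted p = 0.0677 to 0.225). With all 6 it was lost with library totals (0.081 for the male-biased and 0.0537 for the female-biased list), with the heart muscle term described below, which leaves 1 Dicer LKO library against 3 controls (0.0553 for each), and with the replicate number as a block (0.235 for each). Fits without a library, with the heart muscle term or with the block have fewer residual degrees of freedom, which makes the estimated-correlation test stricter. From 0.0491, losing the call in those fits says little about the lists themselves. The preset-correlation call was kept without each library. The same test also called the male-biased list in 7 and the female-biased list in 5 of the 9 other splits of the libraries into 3 and 3 (lowest adjusted p = 1.56e-05 and 0.00116). In all 6 libraries, Y-linked Ddx3y was at 85.1 to 121 CPM, Uty at 28.3 to 34.3, Kdm5d at 23.5 to 27.8 and Eif2s3y at 32.8 to 47 CPM. Xist was at 0.27 CPM or less in each. All 6 thus had the transcripts of male liver. These values argue against a difference in sex between the groups as the source of the shift.

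Erythroid markers were higher as a list, with members going both ways. Of 14 tested, 10 had positive values, 8 rose and 0 fell over all genes, while 9 were higher and 1 lower adjusted over the list alone, with a median log2 fold change of 2.61 (camera adjusted p = 2.7e-18, and adjusted p = 0.084 with an estimated correlation). The beta-globin gene Hbb-bs went from 100 to 755 CPM (log2 fold change 2.91, SE 0.29), Hba-a1 rose by 2.65 and Slc4a1 by 3.90. The split of reads between the near-identical globin genes is uncertain, but all 4 rose, and globin genes took 0.105% to 0.205% of counts in Dicer LKO and 0.020% to 0.028% in the controls. Of the 4 members with negative values, none was called over all genes, among them Alas2 at −0.58 (adjusted p = 0.156, edgeR), which was lower adjusted over the list alone, and Klf1 at −0.55 (adjusted p = 0.363).

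Markers of bile duct cells and of fetal liver were higher as groups. Among 13 ductular markers, 3 rose, 8 were higher adjusted over the list alone and the median was 2.12 (camera adjusted p = 1.74e-08, and 0.232 as adjusted p with an estimated correlation). The chloride channel Cftr rose by 3.74, osteopontin (Spp1) from 31.8 ± 8.50 to 180 ± 62.4 CPM and the adhesion molecule Epcam by 2.48, while the duct transcription factor gene Sox9 had a value of −0.55 and was not called. Of 12 fetal liver genes, 2 rose (Cd24a by 2.63 and Spp1), 7 were higher adjusted over the list alone and the median was 1.54 (camera adjusted p = 8.21e-08, and adjusted p = 0.222 with an estimated correlation). The zinc finger repressor Zbtb20 fell by 1.27 on the log2 scale, from 545 ± 51.7 to 226 ± 16.1 CPM, the only one of 22 hepatocyte transcription factor genes called over all genes (1 higher and 3 lower adjusted over the list alone).

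Macrophage, stellate cell and matrix genes were higher together. All 23 macrophage and Kupffer cell markers had positive values with a median of 0.82, and 2 rose over all genes and 13 adjusted over the list alone (camera adjusted p = 9.23e-14, and adjusted p = 0.232 with an estimated correlation). Trem2 rose by 2.06 and Cx3cr1 by 2.14, although Cx3cr1 overlaps Gorasp1, Wdr48 and Csrnp1, whose reads are not separated from it with certainty. Of 31 collagen and matrix genes, 3 rose, 11 were higher adjusted over the list alone and the median was 0.89 (camera adjusted p = 6.28e-13, and adjusted p = 0.332 with an estimated correlation). Lumican (Lum) went from 7.11 ± 1.71 to 32.4 ± 7.63 CPM, Col6a3 from 15.6 ± 2.53 to 44.6 ± 3.99 CPM and Thbs2 from 3.16 ± 0.194 to 8.07 ± 1.39 CPM. Among 17 stellate cell and fibroblast markers, 3 rose (Lum, Pdgfra by 1.36 and Cygb by 1.01) and 9 were higher and 1 lower adjusted over the list alone (median 0.51, camera adjusted p = 3.21e-07, and adjusted p = 0.054 with an estimated correlation). Vwf was the 1 riser among 18 endothelial markers (1.45), with 4 higher and 1 lower adjusted over the list alone, and the list's call (median 0.12, camera adjusted p = 0.0381, and adjusted p = 0.400 with an estimated correlation) was lost without control replicate 2 or 3, with adjusted p-values up to 0.114. It was also lost with the heart muscle term (0.176). Its median was 0.22 without control replicate 1 and 0.006 with library totals.

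**Figure D2:**
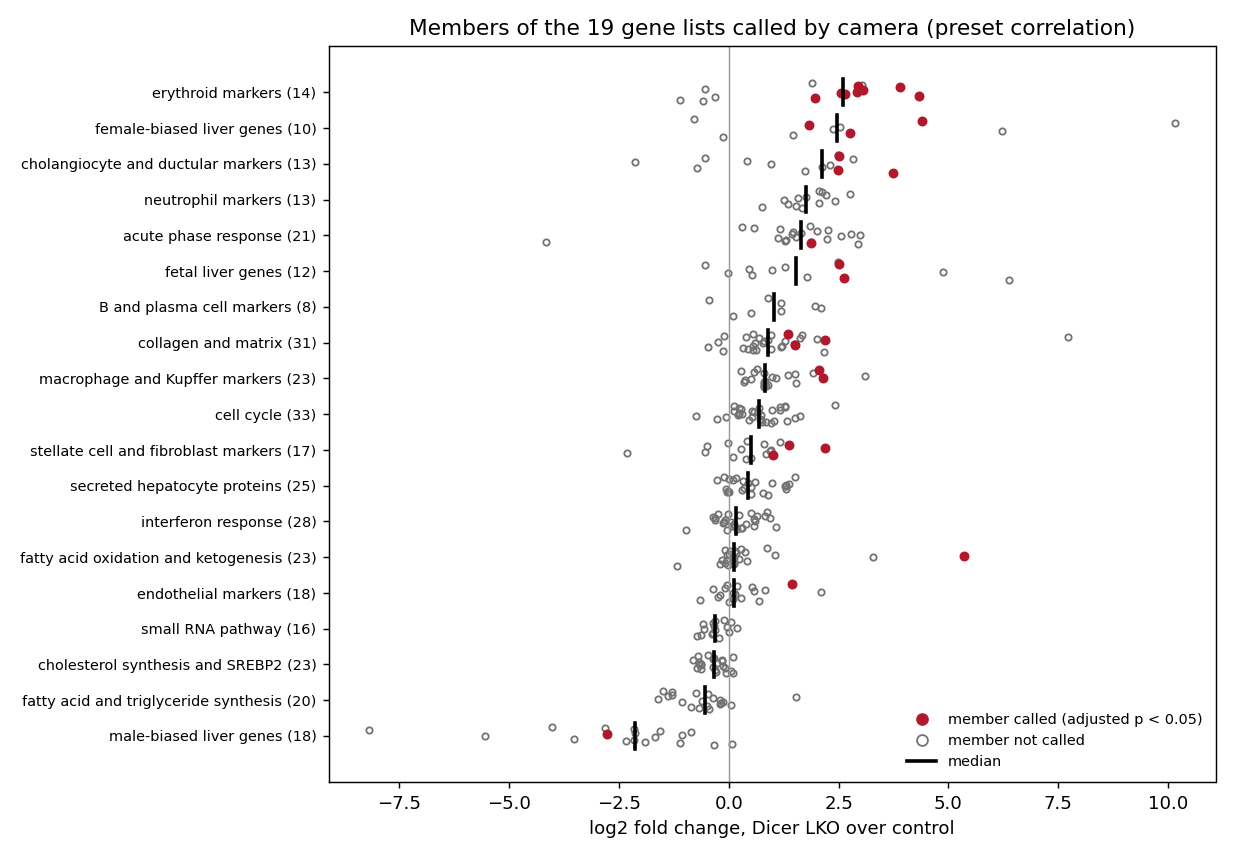
Log2 fold changes (Dicer LKO over control) of the tested members of the 19 gene lists called by camera with the preset correlation, with the number tested in parentheses. Filled points are members called over all genes, open points are members that were not, and bars are medians, which ran from −2.14 for male-biased genes to 2.61 for erythroid markers.

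Inflammation and proliferation lists were higher as groups, with few or no single genes called. The acute phase list (21 genes, median 1.66) had 1 riser, the transcription factor gene Cebpd, which went from 6.55 ± 1.78 to 24.1 ± 7.25 CPM, both over all genes and adjusted over the list alone (camera adjusted p = 4.9e-08, and adjusted p = 0.421 with an estimated correlation). In this list control replicate 2 stood apart from the other controls, with Saa1 at 2910 CPM against 28.8 and 10.1 CPM, and Dicer LKO replicate 2 stood apart in its group, with Saa1 at 8450 against 1840 and 1590 CPM. The median was 2.78 without control replicate 2, 1.17 without Dicer LKO replicate 2 and 0.83 with the heart muscle term, and the list was called in all 3 cases. Neutrophil markers (13 genes, all positive, median 1.77) had 0 called members over all genes and 0 adjusted over the list alone (camera adjusted p = 1.61e-07, and adjusted p = 0.400 with an estimated correlation). Their median was 2.74 without control replicate 2. Cell cycle genes were positive for 30 of 33, with 0 called and 1 adjusted over the list alone (median 0.68, camera adjusted p = 1.73e-05, and adjusted p = 0.405 with an estimated correlation). Their median fell to 0.31 without Dicer LKO replicate 2 (camera adjusted p = 0.00299) and to 0.28 with the heart muscle term (0.0284). B and plasma cell markers (8 genes, 0 called, 1 adjusted over the list alone, median 1.04, camera adjusted p = 0.013, and adjusted p = 0.492 with an estimated correlation) lost their call without Dicer LKO replicate 3 (median 0.51) or control replicate 1, with adjusted p-values up to 0.156. The 28 interferon response genes (0 called, 0 adjusted over the list alone, median 0.16, camera adjusted p = 0.0353, and adjusted p = 0.738 with an estimated correlation) lost theirs without Dicer LKO replicate 1 or 2 or control replicate 1 or 3, with adjusted p-values up to 0.259. They also lost it with the heart muscle term (0.472). Their median was 0.09 and 0.30 without Dicer LKO replicates 1 and 3, 0.40 and 0.07 without control replicates 2 and 3, 0.04 with library totals and 0.07 with the heart muscle term.

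Lipid synthesis genes were lower as groups. The 20 tested genes of fatty acid and triglyceride synthesis had a median of −0.55, with 0 called and 2 lower adjusted over the list alone, and fatty acid synthase (Fasn) was at 264 ± 48.6 against 805 ± 396 CPM (adjusted p = 0.0773, edgeR). The list's call (camera adjusted p = 0.00131, and adjusted p = 0.455 with an estimated correlation) was lost without control replicate 1 (median −0.29, adjusted p = 0.0936) and with the heart muscle term (−0.36, 0.077). The median was −0.36 without Dicer LKO replicate 2. Cholesterol synthesis genes (23, median −0.34, 0 called, 2 lower adjusted over the list alone, camera adjusted p = 0.00178, and adjusted p = 0.551 with an estimated correlation) lost theirs without Dicer LKO replicate 3 or control replicate 2 (median −0.12), with adjusted p-values up to 0.162. The heart muscle term gave a median of −0.75. Fatty acid oxidation and ketogenesis genes (23) were called as higher (median 0.12, camera adjusted p = 0.0353, and adjusted p = 0.593 with an estimated correlation), with Cyp4a14 the 1 riser and 2 higher adjusted over the list alone. This median was −0.004 when only library totals were used for scaling, 0.20 without Dicer LKO replicate 2, and 0.24 and 0.06 without control replicates 1 and 2. The call was lost without Dicer LKO replicate 3 or control replicate 2 (adjusted p up to 0.333) and with the replicate number as a block (0.0773). The 25 secreted hepatocyte proteins had a median of 0.44 with 0 called and 0 adjusted over the list alone (camera adjusted p = 0.000463, and adjusted p = 0.492 with an estimated correlation), with transferrin (Trf) at 45290 ± 18700 against 16040 ± 5544 CPM (adjusted p = 0.105, edgeR). The fatty acid transporter Cd36 rose from 31.4 ± 11.6 to 138 ± 21.6 CPM, the 1 called member of the lipid droplet list over all genes and adjusted over the list alone.

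The 17 lists that camera did not call had adjusted p-values of 0.0599 to 0.955. They were the miRNA host transcripts, reported miR-122 and let-7 targets, imprinted genes, hepatocyte transcription factors, periportal and pericentral genes, lipid droplet, bile acid, glycolysis, gluconeogenesis and glycogen, urea cycle and amino acid breakdown, cytochrome P450 drug metabolism, glutathione and NRF2, p53 response, unfolded protein response, and T and NK cell markers. Periportal Cps1 was at 4297 ± 1794 against 4281 ± 1419 CPM, and pericentral Cyp2e1 at 4677 ± 1725 against 5644 ± 1773 CPM. Adjusted over the list alone, 2 imprinted genes and 1 bile acid gene were higher and 4 bile acid genes lower, miRNA host transcripts and the glutathione list each had 1 higher and 1 lower, and the pericentral and unfolded protein lists each had 1 lower. Median and mean differed in sign for glycolysis (0.22 and −0.06), periportal genes (0.005 and −0.04) and cytochrome P450 genes (−0.15 and 0.06). Leaving out 1 library gave a call for imprinted genes (Dicer LKO replicate 1 or 2 or control replicate 3, lowest adjusted p = 0.0113 by camera), hepatocyte transcription factors (Dicer LKO replicate 2 or control replicate 2 or 3, 0.00683), lipid droplet genes (Dicer LKO replicate 3 or control replicate 3, 0.0108), T and NK cell markers (Dicer LKO replicate 2 or control replicate 2, 0.0222), bile acid genes (Dicer LKO replicate 3 or control replicate 2, 0.0338) and glycolysis (Dicer LKO replicate 1 or control replicate 3, 0.0459). Imprinted genes were also called with library totals (0.0334), the replicate number as a block (0.0478) and the heart muscle term (0.0155). With that term, urea cycle and amino acid breakdown genes had an adjusted p of 0.00804 and hepatocyte transcription factors one of 0.0284, but these values rest on Dicer LKO replicate 3 alone. Urea cycle and amino acid breakdown genes were not called with any 1 library left out. None of the calls in this paragraph passed with an estimated correlation, where the lowest adjusted p was 0.238. Pancreas acinar and skeletal muscle markers had 2 tested members each, too few for the list test. Cela1 of the acinar list fell, and Cela2a was at 4.08 ± 4.89 against 0.269 ± 0.185 CPM (adjusted p = 0.126, edgeR), with 1 higher and 1 lower adjusted over the list alone.

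Skeletal muscle transcripts were present in control replicate 3. Titin (Ttn) was at 3880 CPM there and at 3.27 CPM or less in the other 5 libraries, and all 15 muscle markers were at least 10 times the highest other library. They made up 0.721% of its counts and at most 0.000599% elsewhere. Neither of the 2 tested members, Ttn and Tpm2, was called over all genes or adjusted over the list alone, and 0 of the 79 genes called lower had a value in control replicate 3 of at least 4 times the other controls. A gene high in 1 control only has a wide spread and is hard to call, as Ttn was (adjusted p = 0.207, edgeR). The count of 0 therefore cannot show that this library had no influence. Without control replicate 3, 23 genes were called, against 185 with all libraries. The stellate list's desmin (Des, 4.66 against 23.4 CPM, not called) is also a muscle gene. In addition, the heart muscle genes Myh6 and Nppa had 0 counts in Dicer LKO replicates 1 and 2 and 76 to 120 counts in the other 4 libraries. These 2 libraries are of 1 group only, so no value within them exists, and a fit with a term for this split, which sets Dicer LKO replicate 3 against the controls, called 43 genes (37 higher, 6 lower).

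**Figure D3:**
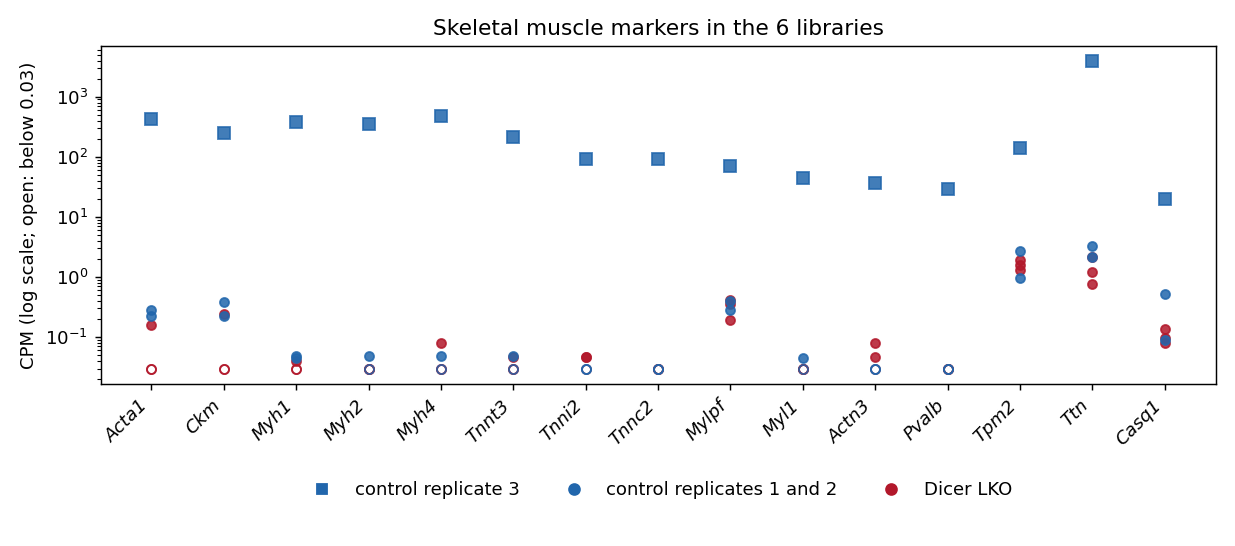
CPM of the 15 skeletal muscle markers in each library (log scale; squares are control replicate 3, circles the other 5 libraries, and open circles values below the axis). Control replicate 3 lay at 3880 CPM for Ttn, where the other libraries were at 3.27 CPM or less.

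Because miRNAs lower the transcripts they bind, genes with miRNA sites were compared with other genes. None of 29 seed families was called by camera, and the same count, 0, came from DESeq2, while limma on TPM called 2 families as lower (miR-25/92 and miR-34). At an unadjusted p under 0.05 there were 6 families, all lower in Dicer LKO, of which miR-34 had the smallest p (0.00973, camera adjusted p = 0.18). Camera, which does not match on untranslated region length, gave this direction for every family except miR-126, also for those not of the liver. Matched lists had medians of −0.0585 to −0.0225, so the shared direction says little about these miRNAs. Without control replicate 1, 1 family was called, miR-34, again as lower. The 1277 tested genes with a site for miR-122, the most abundant hepatocyte miRNA, had a median log2 fold change of −0.03, against −0.04 in matched lists (percentile 77.9, camera adjusted p = 0.471). For let-7 (1502 genes), the median was −0.05 against −0.04 (percentile 20.5, camera adjusted p = 0.199). Medians lay within the central 95% of matched lists for 19 families, below it for 7 and above it for 3. Those above were the liver family miR-26 (−0.03 against −0.06, percentile 99.3) and 2 families not of the liver, miR-1 and miR-375. Those below were the liver families miR-15, miR-22, miR-24, miR-29, miR-34 and miR-103, and miR-124, which is not of the liver. Among them, miR-34 had a median of −0.07 against −0.02. The random lists were not matched on base composition, and its effect on these positions was not tested. A known rise in Dicer LKO was put in by randomly thinning the real control counts of genes with a site. Camera then called miR-122 at 0.2 on the log2 scale (adjusted p = 0.00676) but not at 0.1 (adjusted p = 0.285), and let-7 at 0.3 (adjusted p = 9.61e-06) but not at 0.2 (adjusted p = 0.126).

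Of 22 genes reported as miR-122 targets, 1 rose, the transcription factor gene Klf6 (from 11.6 ± 1.16 to 21.2 ± 0.657 CPM, log2 fold change 0.87, adjusted p = 0.0348, edgeR), and 2 were higher adjusted over the list alone. The list's median was 0.01, and −0.14 when only library totals were used for scaling (camera adjusted p = 0.108). Without control replicate 3 it was 0.25 and the list was called as higher (adjusted p = 0.032), though not with an estimated correlation (adjusted p = 0.381). Its member Aldoa, also a muscle gene, was at 104 ± 36.7 against 99.9 ± 61.6 CPM. Among 21 tested let-7 targets, 0 were called over all genes and 0 adjusted over the list alone, with a median of −0.02 (camera adjusted p = 0.948). The small RNA pathway, which holds the Argonaute and Tnrc6 genes, was lower as a list of 16 (median −0.32, 0 called, 1 lower adjusted over the list alone, camera adjusted p = 0.0158, and adjusted p = 0.405 with an estimated correlation). Its call was lost without Dicer LKO replicate 3 (adjusted p = 0.0508), and Tnrc6b was at 74.7 ± 4.54 against 112 ± 12.6 CPM (adjusted p = 0.0822, edgeR).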

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

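The voom fit with sample quality weights and the term for heart muscle transcripts were chosen only after the data were seen; the other alternatives were planned. All 185 genes kept their sign in every alternative that gave them a value (170 with a CPM of at least 1 and 118 with TPM). This was largely fixed in advance, since the alternatives reuse the libraries from which the genes were picked. The number of genes called moved. It was 103 (50 higher) with library totals, which also moved the median of all genes from −0.01 to −0.13 (log2), 422 (207 higher and the rest, about 2.2e+02, lower) without a filter, 1114 (493 higher, 621 lower) with DESeq2, 41 (21 and 20) with limma on TPM, 787 (236 and 551) with voom weights and 43 (37 and 6) with the heart muscle term, which leaves 1 Dicer LKO library against 3 controls. DESeq2 called all 185 genes again. Leaving out 1 library gave 23 to 389 genes, 15 to 76 higher and 7 to 313 lower, with both extremes of the total from the controls (23 without control replicate 3, 389 without control replicate 1). Dicer1 passed the threshold at −0.98 without a filter (adjusted p = 0.0220, edgeR), at −0.99 with DESeq2 (adjusted p = 0.00117) and at −1.11 with voom weights (adjusted p = 0.0171, limma). With 1 library left out it ranged from −1.15 to −0.79, and over all alternatives its adjusted p ran from 0.00117 to 0.249. Lists called numbered 17 to 22 in the planned settings with all libraries, 16 to 22 with 1 left out, and 2 with an estimated correlation. Of the 19, 12 were called without each library, and all 19 kept the direction given by camera under the other scalings. The median of the fatty acid oxidation and ketogenesis list nevertheless turned from 0.123 to −0.004 with library totals. Seed families called were 2 with limma on TPM, 1 without control replicate 1 and 0 without each other library. Where no cause is named, the cause was not tested. Of 974 comparisons of named genes with all libraries kept, 862 were the same, 67 lost and 17 gained a call, and 28 uncalled values changed sign; with 1 library left out these were 443, 118, 1 and 32 of 594. The replicate numbers did not pair the samples (correlations of same-numbered deviations 0.109, 0.065 and −0.096), and with the number as a block 245 genes were called, 118 of them among the 185, with Dicer1 at −0.97 (adjusted p = 0.0554, edgeR), 19 lists and 0 families. The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05: the real split called 185 genes, 19 lists and 0 families, and the highest of the other splits 0, 21 and 2. Each of the other splits, which mix the genotypes, called at least 8 lists. At this depth and spread, about 29.6% to 35.2% of simulated changes of 1 on the log2 scale were found.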

Other observations

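The tests on muscle transcripts and on miRNA sites, and the tests on heart muscle transcripts, were chosen only after the results were seen, except the ratio of Myh6 to Myh4; the genes named in this part beyond the fixed rule were chosen after their values were seen. The imprinted growth genes of the fetal liver varied widely within Dicer LKO. Igf2 was at 56.7, 4.86 and 132 CPM in Dicer LKO replicates 1, 2 and 3 and at 0.574 CPM or less in every control (log2 fold change 7.39, adjusted p = 0.0855, edgeR). The neighbouring H19 was at 234, 37.2 and 430 CPM, against 0.27, 0.144 and 44.7 CPM in the controls (adjusted p = 0.350), and alpha-fetoprotein (Afp) at 6.05, 0.762 and 112 CPM against 0.768 CPM or less (adjusted p = 0.184). Igf2 was higher in all 3 Dicer LKO libraries than in every control and H19 in 2 of them. The overlap of H19 rests on control replicate 3 (44.7 CPM), which also held skeletal muscle transcripts. Whether these account for that value was not tested, and all 3 Dicer LKO libraries lay above control replicates 1 and 2. Meg3, another imprinted gene, was at 2.1 to 11 CPM in Dicer LKO and 3.92 to 8.6 CPM in the controls.

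Several single genes had values that did not overlap between the groups but were not called. The growth hormone receptor gene Ghr was at 361, 257 and 385 CPM against 718, 554 and 641 CPM (log2 fold change −0.93, adjusted p = 0.0822, edgeR) and Igf1 at 390 to 598 CPM against 607 to 763 CPM (−0.44, adjusted p = 0.307). The steroid hydroxylase gene Cyp17a1 was at 96.5, 410 and 48.5 CPM against 1.62, 4.61 and 1.08 CPM (6.22, adjusted p = 0.0766). The iron hormone hepcidin (Hamp) was at 0.367, 0.143 and 28.1 CPM against 257, 103 and 153 CPM (adjusted p = 0.260). Dicer LKO replicate 2 differed from all other libraries at A2m (54.2 against at most 0.996 CPM), Fgf23 (15.7 CPM against 0 counts in the other 5) and Gsta2 (1.1 against 12.8 to 22.4 CPM). Serpina1e, a male-biased gene with close paralogs, was at 6430 CPM in control replicate 2 and at 5.1 to 8.49 CPM in the other 5 libraries. On chromosome 12, under 1 Mb from Dicer1, other genes also stood apart there, among them Serpina1d (2720 against 462 to 962 CPM), Serpina12 (10.9 against 0.688 to 3.44 CPM), Gm8893 (32.1 against 371 to 977 CPM) and Serpina11 (67.1 against 103 to 218 CPM).

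No set of genes with miRNA sites was called as higher. Without control replicate 3, genes with a miR-122 site lay 0.0095 above matched lists on the log2 scale. The upper bound of this difference was 0.0288, below the 0.1 set as the smallest shift of interest. That bound treats genes as independent and is too narrow, since their estimated correlation was 0.0153 with all libraries. With all libraries, camera did not call a miR-122 rise of 0.1 put into the counts (adjusted p = 0.285). The values thus gave no sign of a shift hidden by control replicate 3, but one near 0.1 stays open. For the 22 reported miR-122 targets such a shift also stays open. Without that library their median went from 0.01 to 0.254 and they were called as higher by camera (adjusted p = 0.032), but not with an estimated correlation (adjusted p = 0.381). Restricting to 8mer sites, which are usually stronger, gave a difference of −0.0304 and an upper bound of 0.007. Genes with 8mer sites thus showed no rise that weak 7mer sites could have hidden, although this bound too treats genes as independent. What also stays open is that miRNA function was retained in part, since Dicer1 reads stood at 50.3% of control, and these reads cannot tell deleted from intact transcript or hepatocytes from other cells. The bounds treat genes as independent and cover miR-122 alone, so small rises of other families stay open (miR-26 lay 0.025 above matched lists, and a let-7 rise of 0.2 put into the counts was not called), and the loss of miRNAs itself was not tested, because small RNAs were not analysed here.

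Skeletal muscle transcripts in control replicate 3 may come from muscle tissue or muscle RNA in that library. Of 20 further muscle genes outside the fixed list, 19 were at least 10 times the highest other library. Exchange of reads with the other 5 libraries was argued against only by the values that had shown the pattern: the highest Ttn value among them was 0.0841% of that in control replicate 3. Heart muscle as an added source stays undecided, with Myh6 at 1.62% of Myh4 there, between the bounds of 1% and 10% set beforehand. No biological explanation was tested, since the design gives none for a single control.

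A sum of 8 listed heart muscle genes was 1.61 and 0.762 CPM in Dicer LKO replicates 1 and 2, where Myh6 and Nppa had 0 counts (which allows up to 0.138 and 0.143 CPM each), and 10.4, 11.2 and 11 CPM in Dicer LKO replicate 3 and control replicates 1 and 2. In control replicate 3, which also held skeletal muscle transcripts, it was 96.5 CPM, of which Myh7, also a gene of slow skeletal muscle, made up 79.2 CPM, so this library was left out of the tests that follow. Genotype stays open: Dicer LKO replicate 3 stood at 0.934 of the mean of control replicates 1 and 2, but it is 1 library and part of the pattern. Reads carried over from a heart library and heart tissue taken with the liver cannot be told apart, because both could give the similar sums (at most 1.079 times apart between these 3 libraries) and the lack of a detectable difference in profile over the 8 genes (simulated chi-square permutation p = 0.976). The split may mark a batch, but Dicer LKO replicates 1 and 2 are of 1 group, and with a term for it 43 genes were called and Dicer1 stood at −1.20 (adjusted p = 0.249, edgeR).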
